A study of Homo sapiens with 6 samples.

How the data were processed

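Per the labels' protocols, THP-1 cells were grown in RPMI medium with 10% serum, seeded at 800000 cells per well and treated with 25 ng/mL PMA. The infected wells received Staphylococcus aureus at a ratio of 1:20 and all wells were kept for 2 h, after which 200 µg/mL gentamicin removed bacteria outside the cells. The labels do not say which part of the ratio stands for the bacteria. From 1 µg of total RNA, ribosomal RNA was depleted and strand-specific libraries were made and sequenced as 150 bp paired-end reads on a HiSeq, per the labels' protocols. RNase R, which removes linear RNA, is not named in them. The groups were taken from the treatment label: 3 infected and 3 mock libraries, whose sample codes carry the numbers 1, 2 and 4. They are called replicates 1, 2 and 3 here.

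The authors deposited 1 table for all 6 libraries. Its first block holds, per the file headers, counts of junction reads per circRNA, which are whole numbers that were not normalized. Its second block holds, per the file headers, log2 CPM values from edgeR. These deposited log2 values equalled those of edgeR's cpm function with a prior count of 2 and TMM factors over all rows, with a largest difference of 4.97e-14, so they carry nothing beyond the counts and were not tested. Positions, host genes, categories and the predicted length in bases stand beside them as deposited annotation. Positions in the table start from 0 and are given here from 1. Per the submitters' processing notes, cutadapt 1.9.3, STAR 2.5.1b and edgeR 3.16.5 were used with genome build hg19. The circRNA caller, its annotation and its filters are not given in the sources used here. Every circRNA of the table had at least 2 reads in some library, so the table appears to have passed a minimum of that kind, and a circRNA with a single read in each of several libraries is not in it. The number of reads sequenced per library, and reads of linear RNA, are not in the sources used here, so a change in a circRNA cannot be set against the mRNA of its gene, and a junction count depends on the gene's transcription as well as on its circularisation. No genome was used. Host gene names are those of the table. Of 2868 names, 57 are numbered loci (G followed by digits), and 2739 matched a current symbol of the RefSeq gene table (GRCh38.p14, used for names only), 155 of them through an older symbol; 7 circRNAs had no host gene and were left out of sums over genes.

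The junction counts were analysed in R 4.3.3 with edgeR 4.0.16. The test was the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) with group as the only term, TMM factors, filterByExpr with min.count 5 and min.total.count 15, and Benjamini-Hochberg adjustment with a threshold of 0.05. This kept 91 circRNAs with 18.3% of the junction reads. The same test on reads summed over the circRNAs of each host gene kept 170 genes with 35.8% of the reads. Such a sum measures the circular output of a gene and not its mRNA. Standard errors are the absolute log2 fold change divided by the square root of F. Positive log2 fold changes mean more in infected cells. Library sizes in the fit were the sums over the tested rows. With library totals in their place and no TMM factors, the median log2 fold change of the tested circRNAs moved by 0.12, from -0.09 to 0.03, and 48 of 91 were above 0 in place of 41.

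The 18 gene lists (897 entries), the 10 circBase identifiers of known circRNAs and the rule for named genes were fixed before the data were examined. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, and an estimated correlation) and with fry, with Benjamini-Hochberg adjustment over the lists. The rule named, in each direction, up to 10 circRNAs past the threshold with non-overlapping groups, filled to 10 by the smallest unadjusted p where fewer passed, which here was all 20. It also named the 5 circRNAs with the highest mean level, the known circRNAs present, and up to 4 tested members of each list with the smallest unadjusted p. It allowed 5 host genes per direction past the threshold, and there were none. Single values per library were compared by exact two-sided permutation tests, whose smallest p with 3 libraries against 3 is 0.1. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which can be technical.

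The 2 groups share their replicate numbers. Across the 91 tested circRNAs, deviations from the group mean correlated between infected and mock libraries of the same number at r = 0.22, 0.49 and 0.50 for replicates 1, 2 and 3, and across the 170 host genes at 0.20, 0.39 and 0.53. As every value was above 0.1, the numbers were taken to pair the samples, by this check and not by the labels. The group means include replicate 3. A shift shared by its 2 libraries therefore raises r between libraries of replicates 1 and 2 of any number, so for these 2 replicates the pairing is an assumption. With the trend on abundance removed, the interval for circRNAs of replicate 1 included 0 (r = 0.184, bootstrap 95% interval -0.030 to 0.385). Replicate 1 did not correlate best with its own number, since infected replicate 1 had r = 0.26 with mock replicate 2. The fit with the number as a block is an alternative. It lowered the biological coefficient of variation from 0.713 to 0.481 for circRNAs and from 0.699 to 0.473 for host genes.

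The test was tested on simulated data before use. Tables of the real size were drawn with 200 changed features each and the observed spread, 5 tables per fold size. The changed features were picked among the most abundant, so they made a large part of those tested (278 of 525 circRNAs at 4-fold). For circRNAs, changes of 2-, 4- and 8-fold were recovered in 1.56%, 19.4% and 78.4% of the changed features tested, and for host genes in 0%, 18.7% and 78.9%. With a coefficient of variation of 0.1 the shares for circRNAs were 47.4%, 95.9% and 100%. A simulation for the replicate block was added after the data were examined: each feature had an effect shared by both libraries of a replicate number, sized by the difference between the squared coefficients of variation observed without and with the block. With the block in the fit, 0.810%, 45.9% and 92.9% were recovered for circRNAs and 1.39%, 41.4% and 94.6% for host genes. The median SE of the fitted log2 fold changes of the real table was 0.95.

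The alternatives set before the data were examined were DESeq2 size factors, library totals, a minimum count of 10, no filter, the replicate block, each library left out in turn, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, other thresholds, exonic circRNAs only, other detection minimums, thinning to the smallest library, the 50 most abundant circRNAs and spliced length. Added after the data were examined were the fit without both libraries of replicate 3, TMM over all rows, the block with a minimum count of 10, and list shares over all junction reads. The contrast of replicate 3 with replicates 1 and 2 was also added then, after these libraries were seen to stand apart, as were the directions of circRNAs and exact sign-flip tests of shares within the 3 pairs. Pseudocounts were not varied, since the tests used counts. Other calculations and the plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.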

Results

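Circular RNAs (circRNAs), closed RNA loops made by joining a downstream splice site to an upstream one, were profiled in macrophages derived from THP-1, a human monocytic leukaemia cell line that takes on macrophage features when treated with phorbol ester (PMA). Cells infected with intracellular Staphylococcus aureus were compared with mock-infected cells, with 3 libraries in each group. The measurement was the number of reads across each back-splice junction in ribosomal RNA-depleted total RNA. The table held 5299 circRNAs from 2868 named host genes and 30202 junction reads. The infected libraries held 6345, 4142 and 4870 junction reads and the mock libraries 3924, 3653 and 7268, in the order of replicates 1, 2 and 3. Levels are given below as junction reads per 10000 junction reads of the library, as mean ± SD with n = 3 per group, and positions are on hg19. With 1 read worth 1.38 to 2.74 of these units, depending on the library, a library with no read of a circRNA still allowed a level of 4.13 to 8.21 (3 reads, counting error only).

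The circRNA pool of these cells was broad and thinly read. The largest number of circRNAs from 1 gene was 18, from BIRC6, an inhibitor of apoptosis that conjugates ubiquitin. ATP8B4, a phospholipid-transporting ATPase, gave 14, and UBAP2 and ARHGAP10 gave 13 each. By annotation, 4251 circRNAs were exonic, 700 overlapped a gene in the sense direction, 323 were intronic, 18 antisense and 7 intergenic, and 3689 (69.6%) carried a circBase identifier. The median circRNA had 3 reads over all 6 libraries, 3283 (62.0%) were read in 1 library only, and 99 were read in all 6.

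The most abundant circRNA was circHIPK3 (hsa_circ_0000284), an exonic circRNA of 1099 bases from the kinase gene HIPK3 on the + strand of chromosome 11, from 33307959 to 33309057. Its level was 128 ± 26.1 in infected and 152 ± 21.7 in mock cells. The next was an exonic circRNA of 153 bases from CMPK1, the gene of a pyrimidine nucleotide kinase, on chromosome 1 from 47838627 to 47838779. It had 91 reads in infected replicate 3, 159 in mock replicate 3 and none in the other 4 libraries. A circRNA of GUSBP1 (hsa_circ_0128780), a pseudogene of beta-glucuronidase, followed with 43.4 ± 22.0 in infected and 83.4 ± 41.8 in mock cells. A circRNA of XPO1 (hsa_circ_0001017), the gene of a nuclear export receptor, had 34.5 ± 9.57 and 47.3 ± 12.5. A circRNA of NFATC3 (hsa_circ_0005615), a calcium-regulated transcription factor, had 38.5 ± 29.9 and 36.3 ± 26.3.

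**Figure D1:**
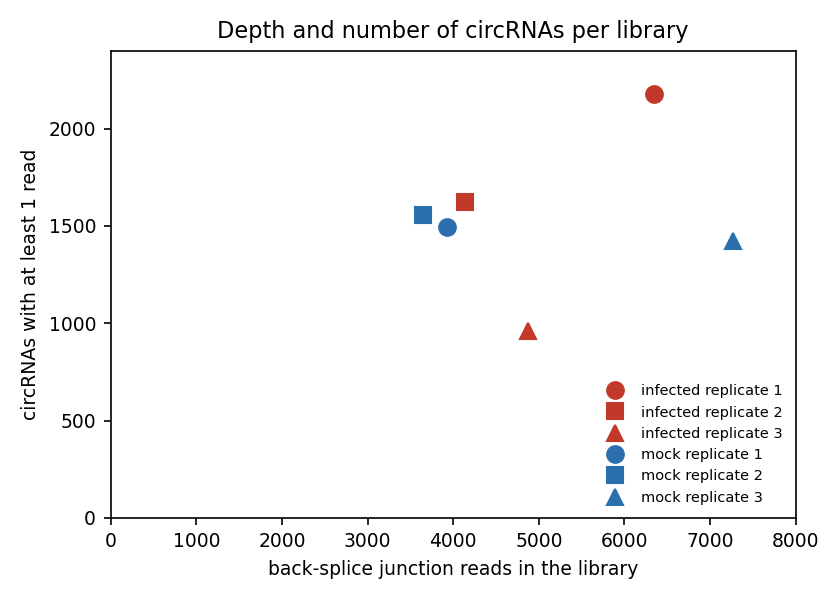
Junction reads (x axis) and number of circRNAs with at least 1 read (y axis) in each of the 6 libraries, coloured by group and shaped by replicate number. The libraries of replicate 3 held 958 and 1425 circRNAs, below the 1496 to 2178 of replicates 1 and 2, although mock replicate 3 had the highest number of reads (7268).

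Both libraries of replicate 3, numbered 4 in the sample codes, stood apart from those of replicates 1 and 2 along the first principal component, which held 55.0% of the variance over the tested circRNAs. The contrast of replicate 3 with the other replicates was chosen after this was seen, on the same circRNAs, so its counts describe the difference and do not test it independently. With group as a covariate, edgeR's quasi-likelihood test gave 5 circRNAs higher and 17 lower in replicate 3 than in replicates 1 and 2, of 91 tested at a Benjamini-Hochberg adjusted p under 0.05, and 6 host genes higher and 27 lower of 170. The filter kept features with enough reads in at least 3 libraries. A circRNA read only in the 2 libraries of replicate 3, such as that of CMPK1, could not pass it, while one absent from both could. The larger numbers on the lower side are therefore no result about direction. The examples that follow were chosen after their values were seen. The circRNA of TBC1D1, the gene of a Rab GTPase-activating protein, had 9 and 11 reads in infected and 13 and 10 in mock replicates 1 and 2, and none in replicate 3. The circRNA of CEP70, a centrosomal protein gene, had 6 and 6 reads in infected and 6 and 8 in mock replicates 1 and 2, and none in replicate 3. Higher in replicate 3 were circRNAs of ARHGAP10, with 28 and 32 reads against 4 to 12, and of RLF, with 22 and 26 reads against 0 to 7.

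The first question was which circRNAs differ in amount between infected and mock cells. None of the 91 circRNAs with enough reads to be tested passed the threshold. In the fit of all 6 libraries, the fitted change furthest below 0 was that of a circRNA of ACVR2A (hsa_circ_0001073), the gene of an activin receptor, from 148653870 to 148657467 on chromosome 2. It had 4, 0 and 7 reads in the infected and 7, 1 and 35 in the mock libraries, a level of 6.89 ± 7.20 against 22.9 ± 23.1 and a log2 fold change of -2.0 (SE 0.96). Without mock replicate 3 this change was -0.74, and with 1 library left out in turn it ranged from -2.89 to -0.74. The GUSBP1 circRNA, on chromosome 5 from 21491430 to 21497305, had a log2 fold change of -1.07 (SE 0.52), with a range of -1.48 to -0.57 with 1 library left out. Within each replicate number its level in infected cells was 0.594, 0.514 and 0.448 times that in mock cells. The circRNAs of ACVR2A, TNFRSF21, RPAP2 and PPP4R1 and the XPO1 circRNA hsa_circ_0001017 were also lower in infected cells in 3 of 3 pairs, and those of MAN1A2, ANKRD17, CCT2, G073721, HOMER1 and ZNF124 were higher in 3 of 3. Some of these directions rest on 1 read or a ratio near 1. In replicate 2 CCT2 had 1 read against 0 and ACVR2A 0 against 1, and ZNF124 had ratios of 1.005 and 1.029 in replicates 1 and 2. Over all 91 tested circRNAs, 8 were higher and 9 lower in 3 of 3 pairs, together 17, where chance gives 20.5 over the 82 without a tie. The fitted change furthest above 0 was that of CCT2 (hsa_circ_0000418), a chaperonin subunit gene, at 1.38 (SE 1.38; 0.68 to 2.24 with 1 library left out). A circRNA of MAN1A2 (hsa_circ_0000119), the gene of a Golgi mannosidase, on chromosome 1 from 117944808 to 117984947, had a level of 27.5 ± 20.7 in infected and 10.8 ± 4.90 in mock cells and a log2 fold change of 1.22 (SE 0.93), which was 0.47 without infected replicate 3.

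All adjusted p-values of edgeR's quasi-likelihood test were 0.990 or above. At an unadjusted p under 0.05 there were 2 circRNAs, ACVR2A and GUSBP1, where chance alone would give 4.55 of 91. This fit leaves any effect shared by a replicate number in its spread, so a count below chance does not argue against a change. With the replicate block edgeR also gave 2 circRNAs at an unadjusted p under 0.05. DESeq2 and limma-voom called 0 circRNAs on the same rows, with 1 at an unadjusted p under 0.05 each. GUSBP1 alone passed in 1 added alternative, with the replicate number as a block and a minimum count of 10 in place of 5: log2 fold change -1.08 and edgeR adjusted p = 4.61e-05 among 33 circRNAs. With the block and the minimum count of 5 its edgeR adjusted p was 0.255. With the minimum count of 10 and no block its edgeR adjusted p was 0.063 among 33 circRNAs. Over all its alternatives the adjusted p ranged from 4.61e-05 to 0.9998. GUSBP1 shares sequence with near-identical copies, so reads could be placed on another copy and its level is uncertain.

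Among the other circRNAs with a positive fitted change, those of ANKRD17 (hsa_circ_0007883), an ankyrin repeat protein gene, and of the numbered locus G073721 (hsa_circ_0131202) were higher in each of the 3 infected than in each of the 3 mock libraries. Chance alone separates the groups, in either direction, in 10% of cases for 3 libraries against 3. ANKRD17 had 23.9 ± 8.14 against 11.5 ± 5.25 and G073721 had 27.4 ± 13.9 against 12.2 ± 3.97. An NFATC3 circRNA (hsa_circ_0000711) had 44.0 ± 29.7 against 24.7 ± 18.9, and one of SATB1, a chromatin organiser gene, 28.4 ± 12.6 against 17.4 ± 15.7. Those of HOMER1, a scaffold protein gene, SCLT1, a centriole protein gene, ASXL1, a chromatin regulator gene, and ZNF124, a zinc finger gene, had log2 fold changes between 0.73 and 1.00, but 0.44, 0.25, 0.0735 and 0.0196 without mock replicate 3. Among those with a negative fitted change, the circRNA of TNFRSF21, the gene of a death receptor, had 10.6 ± 9.30 in infected and 27.6 ± 19.6 in mock cells. An XPO1 circRNA (hsa_circ_0001016) had 7.70 ± 6.69 against 20.1 ± 10.5, and one of PPP4R1, a phosphatase subunit gene, 7.95 ± 7.25 against 18.6 ± 4.61. Those of PPP6R2, another phosphatase subunit gene, RPAP2, an RNA polymerase-associated phosphatase gene, and RBM33, an RNA-binding protein gene, had log2 fold changes of -1.06, -1.54 and -0.72. Without mock replicate 3 those of PPP6R2 and RBM33 were -0.086 and -0.18, and that of RPAP2 ranged from -3.79 to -0.87 with 1 library left out. Of the 20 circRNAs named by the test, 13 had their fold change reduced by a factor of more than 1.5 when 1 library was left out, and 18 were weakest without a library of replicate 3. None of these passed the test. Without both libraries of replicate 3, the sign turned for circHIPK3 (0.051, from -0.44 in all 6), PPP6R2 (0.41) and the NFATC3 circRNA hsa_circ_0000711 (-0.14).

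**Figure D2:**
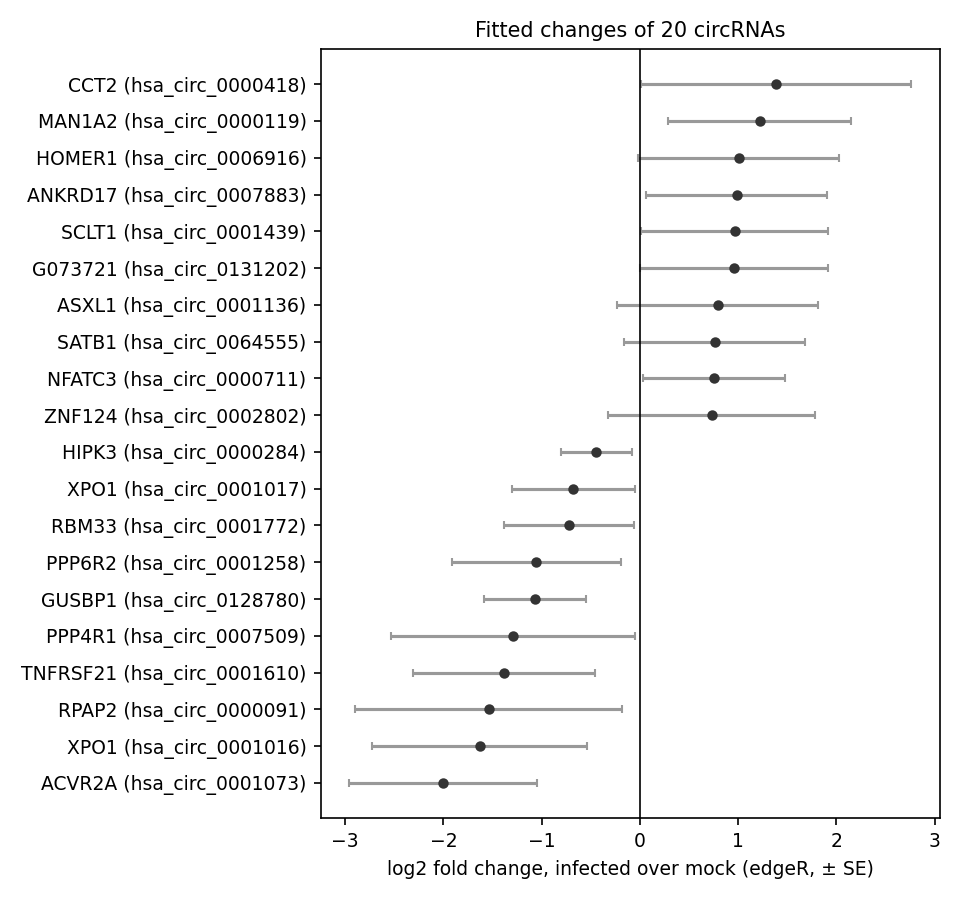
Fitted log2 fold change, infected over mock (x axis), with its standard error (bars), for the 20 circRNAs named by the rule, 10 in each direction, labelled by host gene and circBase identifier (y axis). The points run from -2.0 for ACVR2A to 1.38 for CCT2, and none passed the edgeR threshold.

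Of 10 circRNAs known from other cells and matched by circBase identifier, 9 were in the table. Besides circHIPK3, circZNF609 had 28.3 ± 9.92 in infected and 28.8 ± 6.89 in mock cells, a log2 fold change of -0.18 (SE 0.77). The circRNA circZKSCAN1 had 21.2 ± 11.9 and 14.3 ± 4.30, and circPVT1, from a long non-coding RNA gene beside MYC, had 7.42 ± 6.59 and 9.72 ± 8.62 with no read in replicate 3 of either group. The circRNAs circFOXO3, circFNDC3B, circITCH, circSMARCA5 and circMTO1 were too sparse to be tested. Of these, circFOXO3 had 4 reads in infected replicate 1 and 17 in mock replicate 3, and circMTO1 had 3 reads in mock replicate 3.

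The second question was whether the circular output of whole genes differed, with the reads of all circRNAs of a gene summed. None of the 170 host genes tested passed the threshold in edgeR, where all adjusted p-values were 0.991 or above. At an unadjusted p under 0.05 there was 1 gene, where chance alone would give 8.50, and DESeq2 and limma-voom called 0, with 1 and 4 genes at an unadjusted p under 0.05. As for circRNAs, a count below chance in the fit without the block does not argue against a change. With the replicate block edgeR gave 5 genes at an unadjusted p under 0.05, and its smallest adjusted p was 0.870. The 1 gene of the fit without the block, named after its values were seen, was SPIDR, a scaffold gene of DNA repair. It had 16, 17 and 21 reads in the infected and 2, 4 and 9 in the mock libraries, a level of 36.5 ± 9.79 against 9.48 ± 3.86 and a log2 fold change of 1.79 (SE 0.69). The 4 circRNAs behind this sum were each too sparse to be tested. The most-read of them in infected cells (hsa_circ_0002157), on chromosome 8 from 48196617 to 48206619, had a level of 18.0.

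**Figure D3:**
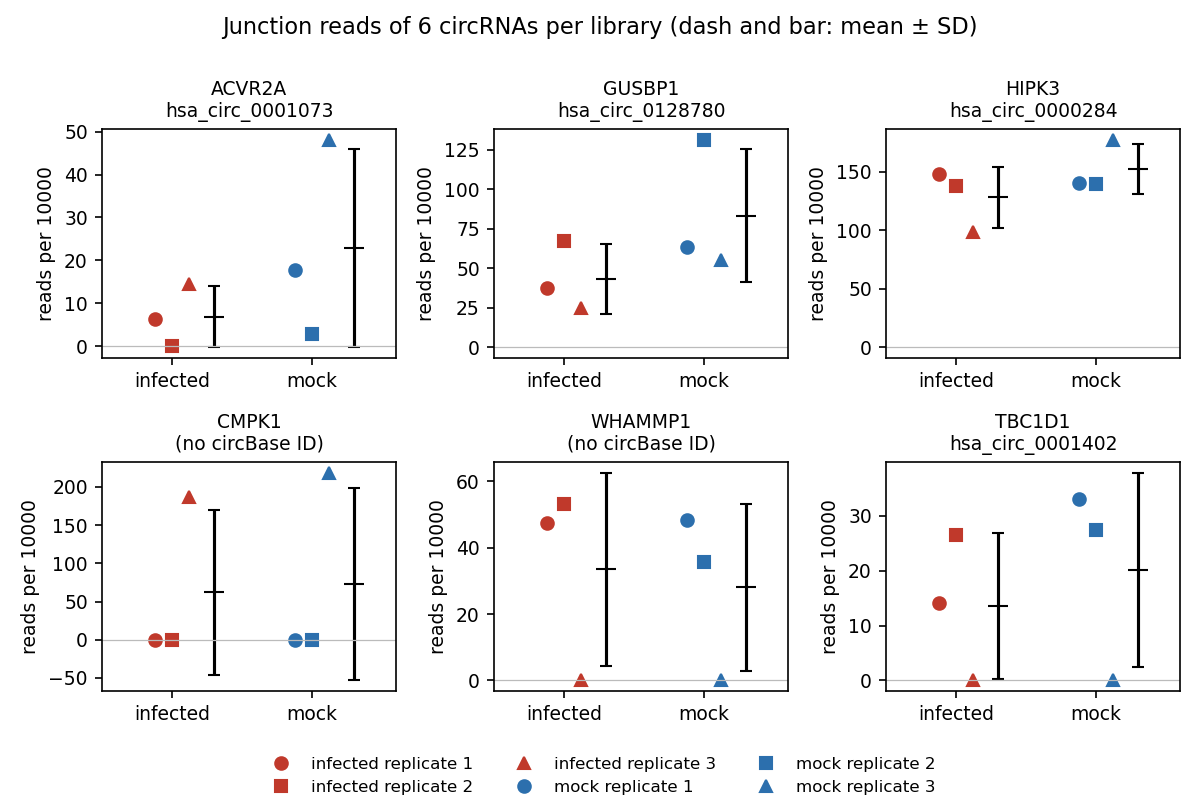
Junction reads per 10000 junction reads of the library (y axis) for 6 circRNAs in the infected (red) and mock (blue) libraries, with the mean and SD beside them (black). The upper row shows ACVR2A, GUSBP1 and HIPK3, whose groups overlap, and the lower row CMPK1, read only in replicate 3 (91 and 159 reads), and WHAMMP1, a pseudogene with near-identical copies, and TBC1D1, both with no read in replicate 3.

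Host genes were grouped by 18 lists. In phagocytosis and actin remodelling, 0 of 5 tested members rose or fell. ARHGAP26 had 40.4 ± 39.8 in infected and 19.1 ± 19.4 in mock cells, and CORO1C, an actin-binding coronin gene, had 28.4 ± 10.8 and 19.0 ± 8.59. ARHGAP10 had 50.8 ± 18.1 and 56.1 ± 21.2, and MYO9B, a myosin gene, 23.3 ± 11.2 and 25.3 ± 11.6. In replicate 3, where circRNAs of this list made 3.699% of junction reads against 2.10% in replicates 1 and 2, ARHGAP26 had 42 and 30 reads against 2 to 13. Other lists had a lower share in replicate 3. Among them were MAP kinase, PI3K and mTOR signalling (0.964% against 2.20%) and interferon and double-stranded RNA sensing (0.288% against 0.675%). In endosome, vesicle and membrane traffic, 0 of 4 passed. DENND4A, a Rab activator gene, had 7.95 ± 7.25 and 15.8 ± 6.84, RABGAP1L, a Rab GTPase-activating protein gene, 19.3 ± 8.87 and 11.2 ± 6.88, PICALM, a clathrin assembly gene, 19.4 ± 6.35 and 21.7 ± 16.1, and VPS13B, a Golgi protein gene, 10.5 ± 7.24 and 11.1 ± 2.52.

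In ubiquitin ligases and deubiquitinases, 0 of 11 passed. UBAP2 had 41.1 ± 12.4 in infected and 20.6 ± 10.6 in mock cells, a log2 fold change of 1.00 (SE 0.60). The ligase genes MIB1 and UBE3A had 16.0 ± 10.3 and 29.6 ± 12.6, and 24.3 ± 13.9 and 36.4 ± 14.9, and the deubiquitinase gene USP3 9.14 ± 4.94 and 16.1 ± 8.31. Among chromatin regulators, 0 of 9 passed. ASXL1 had 28.7 ± 3.55 and 15.5 ± 9.85, higher in each infected library, and SMARCC1, a remodelling complex subunit gene, 7.09 ± 0.870 and 15.6 ± 3.40, lower in each. With 3 libraries against 3, chance alone separates the groups in 10% of cases. The methyltransferase genes SETD3 and SETD2 had 15.7 ± 8.44 and 23.4 ± 20.5, and 19.0 ± 6.05 and 10.4 ± 5.04. In MAP kinase, PI3K and mTOR signalling, 0 of 3 passed. The kinase gene MAP3K4 had 38.8 ± 8.30 and 23.7 ± 14.9, RASA3, a Ras GTPase-activating protein gene, 10.5 ± 14.3 and 22.2 ± 21.9, and the kinase gene STK3 16.7 ± 14.56 and 22.3 ± 15.1. In RNA splicing and circRNA regulators, 0 of 3 passed. RBM33 had 33.7 ± 10.0 and 44.9 ± 18.4, and the RNA-binding protein genes RBM39 and RBM6 had 13.7 ± 11.1 and 17.5 ± 9.88, and 9.91 ± 1.97 and 12.9 ± 0.674. RBM6 too was lower in each infected library.

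No member of these 6 lists passed when adjusted over the list alone. The set test camera gave an adjusted p = 0.835 for each of the 6 lists, and an adjusted p = 0.883 with an estimated correlation. The rotation test fry gave an adjusted p = 0.926 for change in one direction and 0.866 for change in either. For phagocytosis and actin remodelling the mean log2 fold change was 0.15 and the median -0.12. Without both libraries of replicate 3 the sign turned for DENND4A (0.073), MYO9B (0.17) and RBM33 (0.074).

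The other 12 lists had fewer than 3 tested members, so no set test was made for them. Their tested members were few and none passed. IRAK3, which restrains Toll-like receptor signalling, was the tested member of the NF-kB and Toll-like receptor list, with 24.8 ± 17.3 in infected and 15.4 ± 7.20 in mock cells. IFNGR2, an interferon gamma receptor chain, had 25.6 ± 12.2 and 19.7 ± 11.6, LYST, a regulator of lysosome traffic, 20.8 ± 5.35 and 38.0 ± 20.1, and SPI1, the transcription factor PU.1 of myeloid cells, 15.7 ± 18.6 and 12.2 ± 11.5 with no read in replicate 3. In nuclear pore and nuclear transport, XPO1 had 64.5 ± 13.5 and 85.2 ± 24.3 and NUP54 18.3 ± 1.98 and 20.2 ± 11.1. In apoptosis and other cell death, BIRC6 had 31.7 ± 8.601 and 27.1 ± 5.30 and TNFRSF21 12.7 ± 11.9 and 28.5 ± 20.8. ATP5C1, an ATP synthase subunit gene, had 18.3 ± 4.96 and 14.4 ± 12.3, and BRIP1, a helicase gene of DNA repair, 7.91 ± 9.83 and 12.8 ± 4.83. Genes of inflammatory cytokines and the inflammasome gave 8 junction reads in all, 5 of NEK7 in infected replicate 1 and 3 of IL1B in mock replicate 3. Of the lists of other cell types, T and B lymphocyte markers had 2 reads, and the epithelial and fibroblast and the erythroid and megakaryocyte lists had 0 reads of 30202.

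The third question was whether infection altered the size or make-up of the circRNA pool. The libraries held 5119 ± 1122 junction reads in infected and 4948 ± 2013 in mock cells (exact two-sided permutation test, p = 0.8). These totals also depend on sequencing depth, which is not known here, so they do not measure the size of the pool. The number of circRNAs with at least 1 read was 1586 ± 611 and 1493 ± 66.6 (exact permutation p = 0.7). Exonic circRNAs made 85.1 ± 0.851% and 85.1 ± 1.94% of junction reads, sense-overlapping ones 10.9 ± 1.36% and 10.4 ± 2.31%, intronic ones 3.75 ± 0.712% and 4.20 ± 0.597%, antisense ones 0.142 ± 0.1104% and 0.177 ± 0.106%, and intergenic ones 0.0928 ± 0.0824% and 0.09997 ± 0.0902%. The exact permutation p of the 5 categories was 0.6 to 1, and 1 for each after Benjamini-Hochberg adjustment. The 10 most abundant circRNAs of a library took 6.31 ± 0.971% and 6.80 ± 1.39% of its reads (exact permutation p = 0.7), a share lower in infected cells in each of the 3 pairs (exact sign-flip p = 0.25, the smallest possible). None of these measures differed by more than the spread between libraries, and 3 libraries against 3 cannot give an exact p below 0.1.

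Across the 91 tested circRNAs, which are not independent replicates, the fitted log2 fold change had a Spearman correlation of -0.0412 with genomic span, -0.0348 with mean abundance and -0.0587 with the number of circRNAs of the host gene.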

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

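Alternatives chosen after the data were examined were the fit on replicates 1 and 2 only, TMM over all rows, the replicate block with a minimum count of 10, and list shares over all reads. No count of called circRNAs, host genes or lists changed under any alternative, with 2 exceptions for circRNAs: the replicate block with a minimum count of 10 called 1 (GUSBP1), and an unadjusted p under 0.05 with a 2-fold change took 2. The replicate block with the minimum count of 5 changed no call. The cause of the GUSBP1 call was not tested. The spread between libraries limits this: a simulated 4-fold change of a tested circRNA was recovered in 19.4% of cases at the observed spread, and in 45.9% with replicate effects and the block. For named circRNAs and host genes, 308 of 336 values with 1 library left out and 533 of 552 under the other settings kept their sign and side of the threshold. As none of these values passed the threshold in the main fit, a turned sign is no change of result, and the cause was not tested. Categories with no tested circRNA (antisense, intergenic) gave no value on the filtered rows.

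Log2 fold changes that turned sign were as follows. Under the replicate block, hsa_circ_0005615 of NFATC3 had -0.19 (and -0.18 with the minimum count of 10) and PICALM 0.070. With the minimum count of 10 and no block hsa_circ_0005615 had -0.028. Under limma-voom it had -0.20, circPVT1 0.13, PICALM 0.46, RASA3 0.80 and NUP54 0.024. On replicates 1 and 2 only, hsa_circ_0000711 of NFATC3 had -0.14, PPP6R2 0.41, circHIPK3 0.051, circZKSCAN1 -0.11, MYO9B 0.17, DENND4A 0.073, RBM33 0.074, ATP5C1 -0.21 and BIRC6 -0.047. With 1 library left out in turn the ranges were -0.55 to 0.074 for circZNF609, -0.50 to 0.77 for hsa_circ_0005615, -0.040 to 0.65 for circZKSCAN1, -1.03 to 0.36 for circPVT1, -0.55 to 0.13 for ARHGAP10, -0.24 to 2.25 for ARHGAP26, -0.075 to 1.34 for ATP5C1, -0.69 to 0.081 for MYO9B, -0.36 to 0.31 for NUP54, -0.60 to 0.42 for PICALM, -3.14 to 0.072 for RASA3, -0.87 to 0.038 for RBM33, -1.04 to 0.22 for RBM39, -1.20 to 0.39 for SETD3, -0.92 to 1.51 for SPI1, -0.76 to 0.29 for STK3 and -0.48 to 0.21 for VPS13B.

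For whole libraries, the difference infected minus mock turned sign for detected circRNAs with at least 5 reads (-6.67) and after thinning to the smallest library (-2.88), and its range with 1 library left out was -203 to 407. That of junction reads was -477 to 1330, and that of the share of the 10 most abundant circRNAs -1.20 to 0.187 percentage points. For categories it turned on replicates 1 and 2 only for exonic (0.470), sense-overlapping (-0.0335) and intergenic (0.00985) circRNAs and on the filtered rows for intronic ones (0.179), in percentage points, with ranges of -1.02 to 0.909 for exonic, -0.668 to 1.64 for sense-overlapping, -0.0978 to 0.00533 for antisense and -0.0396 to 0.0448 for intergenic ones. The Spearman correlation of the fitted change with spliced length was 0.0247, against a negative value with genomic span.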

Other observations

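Apart from the replicate block and the simulations without it, the tests in this part were chosen after the results were seen. As a share of all junction reads, including circRNAs too sparse to be tested, 16 of the 18 gene lists had reads, and in 2 of them the infected libraries did not overlap the mock libraries. Chance gives this in 10% of cases for 3 libraries against 3. Genes of mitochondria, glycolysis and hypoxia made 0.677 ± 0.107% of junction reads in infected and 0.431 ± 0.0928% in mock cells (30 circRNAs of 21 genes), with reads of ETFA, an electron transfer protein gene, at 12.5 ± 10.9 and 4.44 ± 4.15 per 10000 and of SUCLG2, a citric acid cycle gene, at 7.13 ± 2.81 and 3.53 ± 3.07. Genes of apoptosis and other cell death made 0.583 ± 0.0303% and 0.805 ± 0.233% (36 circRNAs of 11 genes), of which BIRC6 had 31.7 ± 8.601 and 27.1 ± 5.30 per 10000 and TNFRSF21 12.7 ± 11.9 and 28.5 ± 20.8, so the lower share in infected cells did not come from BIRC6. Both had an exact two-sided permutation p = 0.1, the smallest possible, and 0.9 after Benjamini-Hochberg adjustment over the lists. The other lists had an exact permutation p of 0.2 or more, among them NF-kB and Toll-like receptor genes with 0.560 ± 0.181% and 0.389 ± 0.0667%. Within replicate numbers, 5 of the 16 lists went the same way in all 3 pairs. Chance gives 4 without ties and fewer here, since the inflammatory cytokine and lymphocyte lists had tied pairs. The 5 included both lists above. The others were ubiquitin ligases and chromatin regulators, higher in infected cells by 0.333 to 0.409 and 0.0388 to 0.510 percentage points, and autophagy and lysosome, lower by 0.12 to 0.23. The tested host genes of the ubiquitin and chromatin lists leaned the other way. Their median log2 fold changes were -0.41 (6 of 11 negative) and -0.15 (6 of 9 negative). An exact sign-flip test of 3 pairs cannot give a p under 0.25.

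A further 25 circRNAs were read in all 3 libraries of one group and in none of the other, 11 in infected and 14 in mock cells, and the same held for 23 host genes. Of these, with examples chosen after their values were seen, the circRNA hsa_circ_0000220 of FAM188A had 1, 2 and 9 reads in infected cells only and hsa_circ_0003267 of ME1, the gene of malic enzyme, 3, 1 and 7. In mock cells only, hsa_circ_0002371 of CCAR1 had 2, 2 and 9 reads, hsa_circ_0002254 of RANBP2, a nuclear pore gene, 1, 1 and 8, and hsa_circ_0006757 of C6orf106 4, 1 and 5. Summed over a gene, AGO2, the small RNA effector, had 3, 1 and 9 reads in infected cells only, and HSPA9, a mitochondrial chaperone, 4, 1 and 14 in mock cells only. The number of such circRNAs was lower than in any other split of the 6 libraries into 3 and 3: all 10 splits gave at least as many, with 29 to 114 in the others. With the numbers taken to pair the samples, the 3 other splits that part all 3 pairs gave 29 to 39. The 4 splits with both libraries of replicate 3 on the same side gave 68 to 114, and the 5 other splits that part them 29 to 39. Those that part replicate 3 but keep replicates 1 and 2 together gave 33 and 35. The higher counts thus went with replicate 3 and not with the replicate numbers in general. Both its libraries held fewer circRNAs, which by itself can raise the number absent from their side. The design has too few splits for a share under 0.05.

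In the same 10 splits, the real grouping gave 0 called circRNAs and the highest other 1, 0 called host genes and the highest other 0, and 0 called lists and the highest other 1. With a real count of 0, all 10 splits give at least as many whatever they call, so this comparison says nothing about chance, and 10 splits could not give a share under 0.05. The split that gave 12 circRNAs at an unadjusted p under 0.05, against 2 for the real grouping, put both libraries of replicate 3 on the same side. The 3 other splits that part all 3 pairs gave 0 to 1.

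The absence of called circRNAs between infected and mock cells is consistent with wide spread between libraries, since 19.4% of simulated 4-fold changes (54 of 278) were recovered at the observed spread, against 95.9% with a coefficient of variation of 0.1 and the same reads. With replicate effects in the simulated tables and the replicate block in the fit, 45.9% of 4-fold changes (127 of 277) were recovered, and the block called 0 circRNAs in the real table too. A biological absence of change cannot be told apart from a few missed changes of 4-fold or less. Of simulated 8-fold changes, 78.4% were recovered without and 92.9% with the block. The changed circRNAs made a large part of those tested in the simulated tables. All these shares can therefore overstate recovery where few circRNAs change, and a few missed 8-fold changes are not excluded either. The test covered 91 circRNAs with 18.3% of the junction reads. It says nothing about circRNAs too sparse to be tested.

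The other pattern is that levels of tested circRNAs in both libraries of replicate 3 differed from those in replicates 1 and 2. Of 329 circRNAs read in all 4 libraries of replicates 1 and 2, 118 (35.9%) had no read in either library of replicate 3, where separate absences at the same abundance gave 103.8 (95% interval of 5000 permutations 97 to 111). The permutations kept the number of circRNAs absent from each library, 200 and 148, so most joint absences follow from these numbers whatever their cause. Of 5000 permutations, 2 gave 118 or more. The 2 libraries of replicate 3 shared 233 of 2150 circRNAs, against 686 of 2988 and 736 of 2444 in replicates 1 and 2. Few starting molecules, drawn separately in each library, may contribute to both patterns. The joint absences exceeded the interval for separate absences, but abundance was matched only within 10 strata, so the excess does not decide this. Deviations of both libraries, with the trend on abundance removed, correlated at r = 0.465 over 91 circRNAs (bootstrap 95% interval 0.265 to 0.628), against 0.475 in replicate 2, which did not stand apart, and 0.184 (-0.030 to 0.385) in replicate 1. Deviations were taken from means over all 3 replicates, and the r that few starting molecules would give was not simulated. This correlation therefore does not decide whether they account for the difference. Reads from another cell type may contribute as well. Lymphocyte, epithelial or fibroblast and erythroid or megakaryocyte genes had 0 of 12138 junction reads in replicate 3 and 2 of 18064 in the others, too few to decide. Genes of monocyte and macrophage identity made 0.206% of junction reads in replicate 3 and 0.426% in replicates 1 and 2. The share of MAP kinase, PI3K and mTOR genes was lower too (0.964% against 2.20%), so this does not single out cell identity. A separate culture, library preparation or sequencing day for the libraries numbered 4 also stays open, since the labels give none of these.

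Replicate 3 also differed in its low counts. It had 5.08 and 5.10 reads per detected circRNA in infected and mock cells, against 2.34 to 2.91 in the other 4 libraries. Of the circRNAs read in a library that had at least 2 reads in another one, 10.9% and 15.1% had a single read in replicate 3, against 37.9% to 52.9% in the others. The circRNAs read in both libraries of a replicate number and in no other library were 110, 109 and 35 for replicates 1, 2 and 3, but those with at least 10 reads in both were 0, 0 and 4. The 4 were CMPK1, with 91 and 159 reads in infected and mock cells, EP300 (hsa_circ_0116608) with 12 and 20, PVRL3 (hsa_circ_0066776) with 12 and 19, and MAML2 (hsa_circ_0024085) with 12 and 13. VEGFC (hsa_circ_0004496), a growth factor gene of lymphatic vessels, had 6 and 5 reads, in replicate 3 only. In the opposite direction, the circRNA of WHAMMP1, a pseudogene with near-identical copies and therefore of uncertain level, had 30 and 22 reads in infected and 19 and 13 in mock replicates 1 and 2, and none in replicate 3. GSE1 had 9 and 11 and 2 and 17 reads, and CAPZA1, an actin capping protein gene, 11 and 13 and 5 and 6, with none in replicate 3.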
